A study of Homo sapiens with 10 samples.

How the data were processed

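PolyA RNA of human embryonic stem cells (WAe009-A, also called H9) was sequenced with 150 paired-end cycles on a NovaSeq-6000, per the labels' protocols, in 5 libraries labelled as KCNH2 knockout and 5 of wild type. Groups and replicate numbers were taken from the sample titles, which differ within a group only in the replicate number. Per the labels, the groups grew in different media, which no model can separate from genotype. The authors deposited raw counts per gene for the 10 libraries, with no normalization, and the totals differ between libraries as raw counts do. The submitters' processing notes name hg38, DESeq2 and R 3.6.3. The aligner, counting tool, annotation and strand setting are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies may be shared. The authors' deposited table of knockout against WT holds a mean normalised signal per gene, a log2 fold change with its standard error (in log2), a score that is their quotient, and a p-value with its adjusted p-value. Its log2 values look shrunken towards 0, because standard errors fall for genes with few counts. That table was used only for gene symbols and for the comparison of fold changes.

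The count table held 32152 genes, none at 0 in every library, and 31146 had a position in GENCODE 29 (GRCh38, the same assembly as hg38). Library totals ran from 28615751 to 47319933 counts. A count of 0 in a library allows up to 3 counts, which is 0.0634 to 0.105 CPM at these depths. Intervals and floors cover counting error only, since the counts carry no molecular identifiers. For pairs of libraries in a group, the chi-square per degree of freedom over genes with at least 20 counts lay between 3.59 and 26.2. That is above sampling noise, and each library was counted as 1 replicate. Separate preparations of the same culture could also exceed that noise, so this does not show separate cultures.

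Genes were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest on group, TMM scaling, filterByExpr), with Benjamini-Hochberg adjustment over 19163 genes and a threshold of 0.05. CPM values use TMM-scaled library sizes. Log2 CPM values use a prior count of 2. A total of 34 gene lists had been fixed before the data were examined, as had the tests, the named genes and the first set of alternatives. They were tested with camera (limma 3.58.1, correlation preset at 0.01) on 33 lists with at least 3 tested genes, and again with an estimated correlation. With an estimated correlation none of the 6 called lists passed (adjusted p from 0.241 to 0.441). The planned test fry (limma) asks whether a list's members changed, without setting them against other genes. It gave the 6 called lists adjusted p from 2.86e-07 to 0.00131. Lists that camera did not call passed fry too, such as pluripotency (0.000228), so fry was not used for calls. Where an older symbol was listed, it was matched through a table of names. Chromosome scores are the mean over tested genes of centred log2 CPM per library, compared by an exact permutation test with scipy 1.17.1 and numpy 2.4.6 in Python 3.11.15. The Y chromosome was not used.

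Named genes are KCNH2, then the 12 largest rises and 12 largest falls among genes with adjusted p under 0.05, at least 5 CPM in the higher group, no overlap between the 5 and 5 libraries and no clone-style name of the listed forms, then up to 4 members with the smallest p per list. Of the genes so chosen, 1 is not reported here. Some other genes are named as chosen after their values were seen. Against a group at 0, a fold is a lower bound from 3 counts over the group. With 1 to 3 counts it is a ratio with an exact 95% interval. These folds use total counts without TMM scaling, unlike the CPM values.

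The alternatives planned before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma voom, no filter, a filter of 1 CPM in 5 libraries, a replicate block, a test against a log2 fold change of 1, and leaving out each library. Added after seeing the data were fits without both replicate 3 libraries, without knockout 3, WT 2 and WT 3, with 1 surrogate variable (sva 3.50.0), and with a correction for gene length and GC. That correction fitted a smooth trend of each library's log2 CPM on length and GC (natural splines with 5 degrees of freedom, protein-coding genes of at least 1 CPM) and entered it as an offset. It was run first with the union of exons as the length. It was run again with the length of 1 transcript per gene after the first result had been seen, because the union of exons overstates the length of ribosomal protein mRNAs, and the results of both are given. Length and GC were known for 98.9% of tested genes. A further 4 lists (metallothioneins, actin and SRF targets, YAP/TAZ targets, MHC class I presentation) were chosen after values had been seen and appear only among the closing observations.

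The fitting steps were tested on simulated counts made from the real means and library sizes for this comparison. Over 18865 genes, the test recovered 46% of 50 genes changed 1.25-fold, 48% at 1.5-fold, 62% at 2-fold and 96% at 4-fold, with 2 false calls among 140 (1.43%). A list of 20 further genes was raised as well, and those of them that were recovered are among these calls. Far fewer genes were changed than the 8816 called in the real data, which makes the adjusted threshold stricter. Genes were also drawn independently. These shares check the steps and do not carry over to the real comparison.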

Results

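The data were polyA RNA-seq libraries of human embryonic stem cells of the line WAe009-A, also called H9. There were 5 libraries of cells labelled as knockout of KCNH2 and 5 of wild-type (WT) cells. KCNH2 encodes hERG1, the pore-forming subunit of a voltage-gated potassium channel that repolarises the heart. The series asks which transcripts depend on KCNH2 in undifferentiated cells. The labels name the edited cells as a knockout in the titles and the growth protocol but as a knockdown in the genotype field, and "knockout" is used here. Per the labels, WT cells grew in TeSR-E8 and the knockout cells in mTeSR Plus, so medium and genotype go together in every library. Libraries held 29788732 to 40587206 counts in the knockout and 28615751 to 47319933 in WT. CPM below are counts scaled to the TMM-adjusted library size, per 1e6 counts. On log2 CPM, the first principal component held 44.8% of the variance and separated the groups, from -40.3 to -14.5 in the knockout and from 18.4 to 54.0 in WT. Knockout replicate 3 stood apart on the second component, which held 28.3%, at -59.1 against -2.3 to 13.9 in the other knockout libraries. WT replicates 3 (-32.2) and 2 (-10.1) lay on the same side, against 25 to 35.8 in the other WT libraries. Many genes with the largest loadings on this component had pseudogene names, such as NPM1P32 and RPL7P44, beside others such as SYNC and CAT. What the component reflects was not tested. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Values below are means ± SD over 5 libraries in each group. Adjusted p-values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of lists are from limma's camera.

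KCNH2 mRNA was lower in the knockout, though most of it remained. It measured 12.2 ± 1.001 CPM (SD, n = 5) in the knockout and 15.5 ± 0.75 CPM in WT, a log2 fold change of -0.35 (SE 0.06, edgeR adjusted p = 6.48e-04). The knockout libraries held 11.15, 13.19, 13.16, 12.15 and 11.19 CPM and the WT libraries 14.88, 16.12, 14.66, 16.39 and 15.41 CPM, without overlap. The gene (ENSG00000055118) spans chromosome 7, 150944961 to 150978315, on the minus strand of GRCh38. Counts over a whole gene can include reads from outside an edited part, and the position of the edit is not given in the sources used here, so the mRNA level does not check the loss of the protein. Of 17 tested genes near KCNH2 on 7q36, 5 rose and 7 fell (camera adjusted p = 0.556); CHPF2 fell by 0.59 on the log2 scale and RHEB rose by 0.16.

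**Figure D1:**
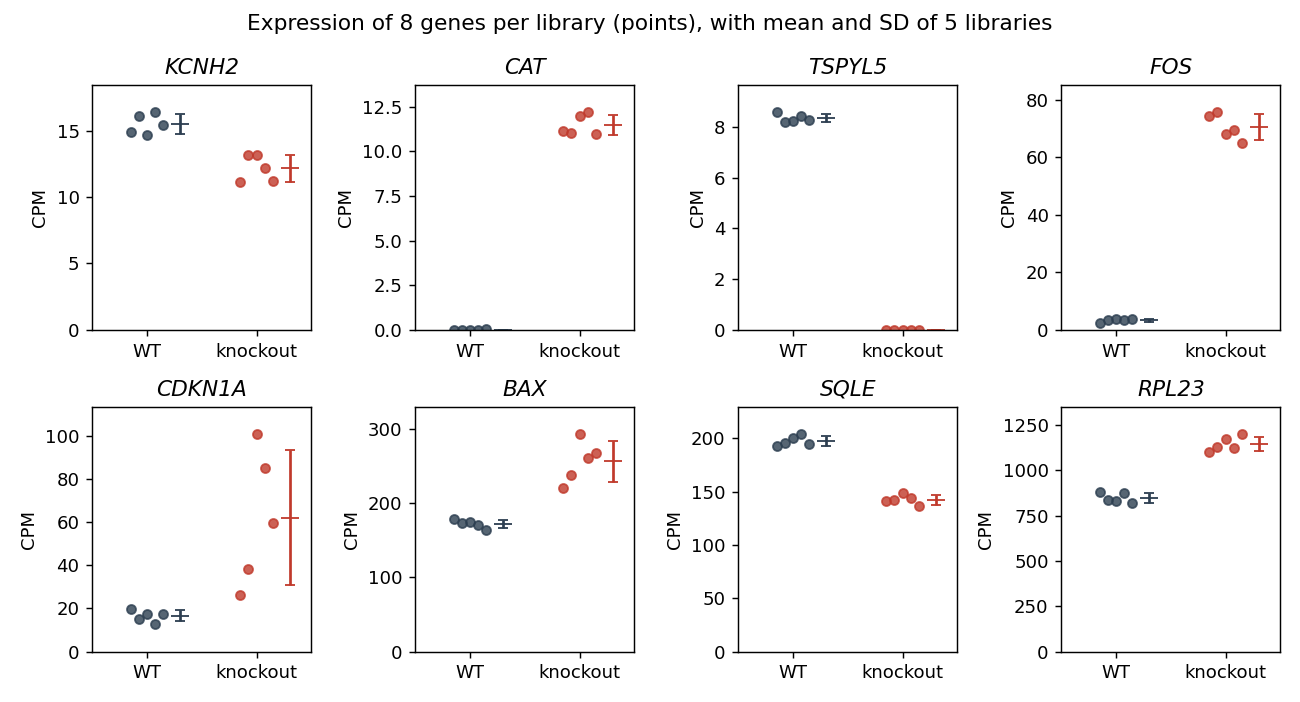
Expression of 8 genes in CPM (vertical axes, linear, from 0) in each of 5 WT and 5 knockout libraries (points), with the mean and SD beside them. KCNH2 lies between 11.15 and 13.19 CPM in the knockout and between 14.66 and 16.39 CPM in WT, and CDKN1A spreads from 26.2 to 100.9 CPM within the knockout.

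Several genes went between near silence and clear expression. CAT, which encodes the peroxide-degrading enzyme catalase (chromosome 11, 34438925 to 34472062), measured 11.5 ± 0.57 CPM in the knockout, with 2022 counts there and 1 in WT, a ratio of 2160 over unscaled library totals (95% counting interval 387 to 85200). PNPLA4, a lipid hydrolase gene on the X chromosome, had 2581 counts in the knockout and 1 in WT, a ratio of 2750 on the same scale (494 to 109000). In the other direction, TSPYL5 (chromosome 8, 97273474 to 97277964) had 0 counts in all 5 knockout libraries and 1640 in WT (8.34 ± 0.16 CPM). Over unscaled totals that is at least 512-fold lower against a floor of 3 counts over the group. MAOA, which encodes a monoamine-degrading enzyme, fell from 12.5 ± 0.81 to 0.39 ± 0.11 CPM, and PKIB, an inhibitor of protein kinase A, from 34.7 ± 2.19 to 0.68 ± 0.29 CPM. Both had adjusted p-values under 1e-09 (3.53e-10 and 4.96e-10). SYT11, a synaptotagmin gene, had a log2 fold change of -5.25 (SE 0.16) and BEX5 one of -6.06, from 6.69 ± 0.61 to 0.097 ± 0.038 CPM. CYP2R1, a vitamin D hydroxylase gene, rose by 6.105 (SE 0.16), and NHLH2, a neuronal transcription factor gene, by 3.54 (SE 0.10). SYNC rose by 3.84, from 0.52 ± 0.55 to 7.92 ± 3.73 CPM. Its libraries were uneven, from 0.0 to 1.323 CPM in WT and from 4.869 to 13.96 CPM in the knockout. The authors' deposited table gives it a log2 fold change of only 0.29. TYW1B rose by 3.58 and LRRC37A11P by 4.02, but both have near-identical copies between which reads may be split. The clone-named transcript Z99496.2 rose by 7.65. Also among the genes with the largest falls were TRIM61 (-5.52), SIX6 (-4.02), ZNF562 (-3.64), APLNR (-2.68), ZNF876P (-2.64), ATP10B (-2.28) and GJA5 (-2.16).

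Across 19163 tested genes, 4201 were higher and 4615 lower in the knockout at an adjusted p under 0.05, of which 253 and 371 changed by more than 1 on the log2 scale. The count past 1 depends on the filter: without one it was 411 higher and 597 lower, and with at least 1 CPM in at least 5 libraries 166 and 220. Tested against a log2 fold change of 1, 83 were higher and 93 lower. The 5 and 5 libraries did not overlap for 6514 genes (34.0%), where chance gives 0.79%.

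The targets of the tumour suppressor p53 rose together. Of 24 tested, 23 rose and 0 fell, with a median log2 fold change of 0.58 (camera adjusted p = 2.81e-07; adjusted p = 0.441 with an estimated correlation). BAX, a pro-apoptotic gene, rose from 172.2 ± 5.52 to 256.2 ± 28.0 CPM (adjusted p = 2.72e-05), PHLDA3 from 32.2 ± 2.38 to 69.5 ± 13.7 CPM, and the pro-apoptotic BBC3 from 24.0 ± 2.03 to 50.8 ± 12.8 CPM. SESN1 rose by 0.71. CDKN1A, which encodes the cell cycle inhibitor p21, rose by 1.91 (SE 0.32), and its knockout libraries ranged from 26.2 to 100.9 CPM while WT held 16.5 ± 2.57 CPM. GDF15, chosen after its values were seen, measured 82.7 ± 69.9 CPM in the knockout and 8.18 ± 1.96 CPM in WT. The mean log2 score of the list over WT was 0.32, 0.49, 1.04, 0.92 and 0.72 in knockout replicates 1 to 5, so the list was higher in 5 of 5 libraries but by unequal amounts.

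Of 29 tested apoptosis genes, 12 rose and 5 fell (camera adjusted p = 0.0972), with BAX, BBC3 and PMAIP1 shared with the p53 list. XIAP, which blocks caspases, rose by 0.71 (SE 0.04) and CYCS, cytochrome c, by 0.37, while the pro-apoptotic BOK and BMF fell by 0.73 and 0.60. No proliferation list passed the camera threshold. Of 20 G1/S and replication genes, 8 rose and 2 fell (adjusted p = 0.131), among them PCNA (0.28), CDT1 (0.28), SLBP (0.24) and MCM3 (0.12). Of 21 mitotic genes, 11 rose and 4 fell (adjusted p = 0.131), with UBE2C at 0.27 and CCNB1 at 0.16 but MKI67 at -0.39 and CENPE at -0.22. After the correction for gene length and GC, 4 rose and 2 fell with exonic length, and 5 rose and 1 fell with transcript length. The median went from 0.102 to 0.025 and 0.038. Of 13 D cyclin, CDK and inhibitor genes, 5 rose and 1 fell (adjusted p = 0.0972): CDKN1A rose by 1.91, CDK6 by 0.67 and CDKN1C by 0.57, and CCND1 had a log2 fold change of -0.28. Their median log2 fold change was 0.14 and their mean 0.29, which CDKN1A raised.

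Genes of cholesterol synthesis and uptake fell together. Of 24 tested, 20 fell and 0 rose, with a median of -0.31 (camera adjusted p = 4.00e-07; adjusted p = 0.241 with an estimated correlation); adjusted over the list alone, 20 fell and 1 rose. SQLE, an early enzyme of sterol synthesis, fell from 197.3 ± 4.73 to 142.4 ± 4.67 CPM (adjusted p = 2.68e-07), and CYP51A1 from 110.4 ± 4.19 to 79.2 ± 3.54 CPM. INSIG1, a sterol-regulated gene, fell by 0.51 and IDI1 by 0.49. Fatty acid synthesis moved the same way: 13 of 16 fell and 0 rose (median -0.26, camera adjusted p = 2.18e-05; adjusted p = 0.274 with an estimated correlation), or 14 and 1 adjusted over the list alone. FASN, fatty acid synthase, fell from 1448 ± 50.9 to 1054 ± 53.9 CPM, SREBF1 by 0.61, PNPLA3 by 0.82 and ACSL3 by 0.32. These lists differ between cells that also differed in medium.

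The cytosolic ribosomal protein genes rose: 78 of 83 tested, with 0 lower and a median of 0.33 (camera adjusted p = 8.87e-25; adjusted p = 0.274 with an estimated correlation), and 79 adjusted over the list alone. RPL23 rose from 848.4 ± 26.7 to 1146 ± 39.9 CPM, RPL34 by 0.37, RPL32 by 0.40 and RPS26 by 0.35. Reads of these genes may be shared with their many processed pseudogenes. Fold changes also followed gene length. Over 11343 protein-coding genes of at least 5 CPM, the log2 fold change had a Spearman correlation of -0.43 across genes with transcript length (-0.37 with the union of exons), and genes are not independent replicates. Median log2 fold change went from 0.22 in the shortest 10% of genes to -0.13 in the longest 10%. Ribosomal protein transcripts are short, at a median of 1017 bases against 2702 over tested genes. When each library was corrected for length and GC, the ribosomal median was 0.26 with exonic length and 0.15 with transcript length (camera adjusted p = 4.56e-19 and 3.50e-11), with 73 and 61 of 83 higher and 3 and 5 lower.

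**Figure D2:**
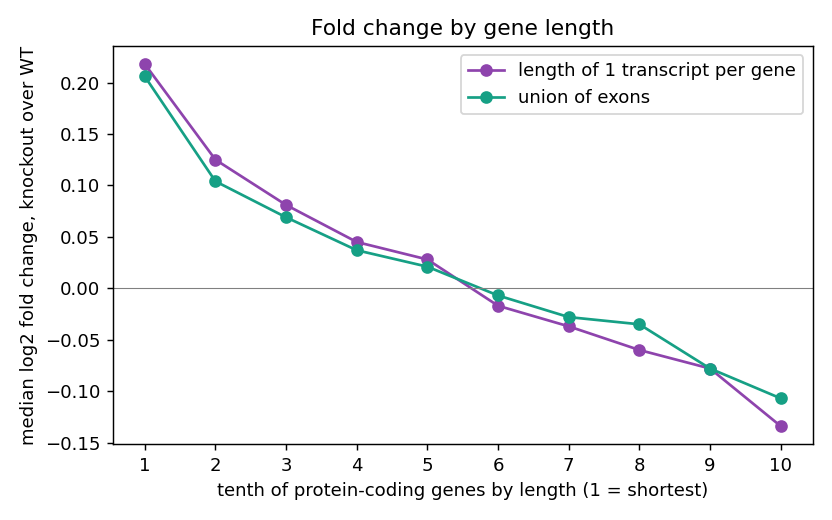
Median log2 fold change (knockout over WT, vertical axis) in 10 equal bins of 11343 protein-coding genes ordered by length (horizontal axis), with length taken from 1 transcript per gene or from the union of exons. The median goes from 0.22 to -0.13 by transcript length and from 0.21 to -0.11 by the union of exons.

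Of 34 tested potassium channel genes, KCNH2 among them, 15 fell and 2 rose (median -0.35, camera adjusted p = 0.0153; adjusted p = 0.241 with an estimated correlation). KCNS3, a potassium channel subunit gene, fell from 25.8 ± 0.81 to 20.3 ± 0.65 CPM, KCNAB3 from 8.56 ± 0.59 to 5.71 ± 0.71 CPM, and KCND3 had under 1 CPM in both groups. After the length correction the list's adjusted p was 0.0488 with exonic length and 0.0558, no longer past the threshold, with transcript length, and its median was -0.25 and -0.24, with 14 members lower under each. Of 28 calcium, sodium and pacemaker channel genes, 16 fell and 7 rose (adjusted p = 0.0512). This list passed with DESeq2 size factors (adjusted p = 0.0413), the stricter filter (0.0378), the replicate block (0.038) and 1 surrogate variable (0.0478), but not after the length corrections (0.296 and 0.304) or with an estimated correlation (0.465). CACNA1B fell from 13.8 ± 0.60 to 5.49 ± 0.46 CPM, CACNA1H by 0.61, SCN9A by 1.07 and SCN1A by 0.91 on the log2 scale.

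**Figure D3:**
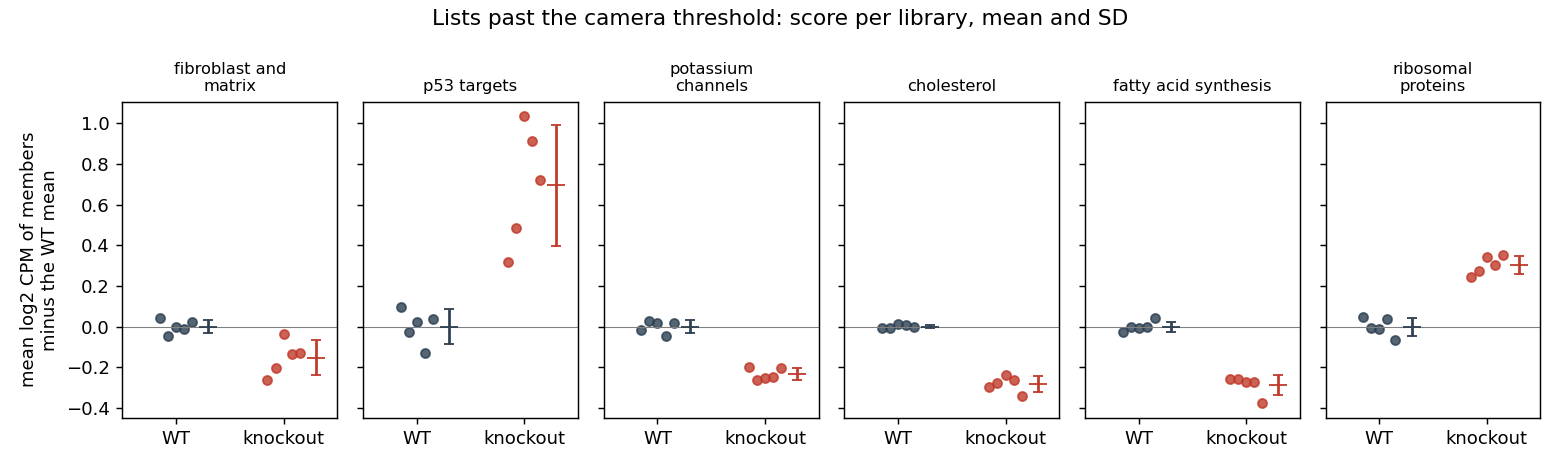
Mean log2 CPM of each list's tested members minus the WT mean (vertical axis) in 5 WT and 5 knockout libraries (points), with mean and SD, for the 6 lists past the camera threshold. The p53 scores spread from 0.32 to 1.04 in the knockout, and the cholesterol scores lie between -0.34 and -0.24.

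Of 22 tested pluripotency genes, 10 rose and 2 fell (camera adjusted p = 0.0972). POU5F1 measured 3214 ± 229.1 CPM in the knockout and 2617 ± 64.0 CPM in WT, FGF2 rose by 0.36, DPPA2 by 0.61, and TERT, the telomerase subunit, had a log2 fold change of -0.31. SOX2, chosen after its values were seen, measured 285.3 ± 30.1 CPM in the knockout and 287.1 ± 12.1 CPM in WT (adjusted p = 0.916). Of 7 naive-state genes, 3 rose (adjusted p = 0.0972): SUSD2 (0.50), KLF4 (0.66) and KLF5 (0.53), while DPPA5 stood at 0.55 with adjusted p = 0.172. Of 8 primitive streak genes, 4 rose and 0 fell (adjusted p = 0.142). In knockout replicate 1 the list's mean log2 score lay within the WT range (-0.147 to 0.157), against 0.459 to 0.815 in the other knockout libraries. WNT3 rose from 0.61 ± 0.11 to 3.97 ± 1.24 CPM, NODAL by 0.88, CER1 by 0.91 and FGF8, at 0.59 CPM, by 1.35.

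Lineage markers moved both ways. Of 9 cardiac and lateral mesoderm genes, 3 rose and 2 fell (adjusted p = 0.467): ACTC1, cardiac actin, rose from 10.3 ± 0.44 to 41.4 ± 11.4 CPM and MYL7 by 1.47, while MYH6 fell by 1.81 and RYR2 by 0.60. Of 8 endoderm genes, 3 rose and 2 fell (adjusted p = 0.963; median 0.003, mean -0.16, test downwards), with FOXA2 at -3.23, FOXA3 at 0.25 and PRDM1 at 1.56. Of 11 neural genes, 3 rose and 7 fell (adjusted p = 0.244). STMN2 rose by 2.34 and GAP43 by 0.53, while SIX6 was at -4.02 and SOX3 fell from 52.6 ± 2.06 to 40.2 ± 1.098 CPM. Of 11 neural crest genes, 2 rose and 4 fell (adjusted p = 0.467), or 2 and 5 adjusted over the list alone; NGFR fell by 0.58, SOX9 by 0.55, B3GAT1 by 0.17 and PAX7, at 0.23 CPM, by 1.06. Of 6 trophoblast and amnion genes, 4 rose and 2 fell (adjusted p = 0.653; median 0.18, mean -0.14, test upwards): GABRP fell from 22.7 ± 2.44 to 6.62 ± 0.42 CPM and KRT7 by 0.63, and KRT8 rose by 0.18 and IGFBP3 by 0.78. Of 17 fibroblast and matrix genes, 11 fell and 3 rose (camera adjusted p = 0.0397; adjusted p = 0.279 with an estimated correlation). COL5A2, a fibrillar collagen gene, fell from 88.6 ± 3.14 to 47.5 ± 3.53 CPM, COL1A1 by 0.52, COL5A1 by 0.71 and COL1A2 by 0.74. This call was lost after either length correction (adjusted p = 0.115 and 0.156), under the stricter filter (0.0663), with 1 surrogate variable (0.0528) and without knockout replicate 1 (0.0719). Of 9 endothelial and blood genes, 5 fell and 2 rose (adjusted p = 0.244), ERG at -2.34, VWF at -1.15, CDH5 at -0.995 and TEK at 0.58.

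Immediate early genes rose in part. Of 16 tested, 10 rose and 4 fell (camera adjusted p = 0.0536), or 11 and 4 adjusted over the list alone. The list passed in 8 of 10 fits that left out 1 library (adjusted p = 0.0227 to 0.044 there) and with 1 surrogate variable (0.0344), but not with an estimated correlation (0.274) or after the length corrections (0.105 and 0.0722), where its median moved little (0.516 before, 0.499 with exonic and 0.543 with transcript length). FOS rose from 3.44 ± 0.52 to 70.6 ± 4.44 CPM (log2 fold change 4.36, SE 0.09), EGR1 from 9.52 ± 0.65 to 68.7 ± 8.06 CPM and FOSB by 4.58, while HSPA1A, a heat shock gene, fell from 68.3 ± 0.83 to 31.9 ± 3.69 CPM. Of 17 FGF/ERK targets, 3 rose and 7 fell (adjusted p = 0.435; median -0.05, mean 0.16, test downwards): FOSL1 rose by 1.71, DUSP6 fell from 655.0 ± 28.2 to 464.0 ± 58.1 CPM and SPRY2 by 0.32. Of 12 BMP targets, 4 rose and 2 fell (adjusted p = 0.236), with ID1 up from 22.9 ± 1.52 to 69.6 ± 7.04 CPM, ID2 at 0.21, ID3 at -0.23 and SMAD9 at -0.74. Of 9 WNT targets, 2 rose and 3 fell (adjusted p = 0.448), or 2 and 4 adjusted over the list alone; APCDD1 fell by 1.04, NKD1 by 0.60, ZNRF3 rose by 0.22 and LEF1, at 0.54 CPM, by 0.69. Of 23 ATF4 and unfolded protein response genes, 11 rose and 2 fell (adjusted p = 0.0972), or 12 and 3 adjusted over the list alone, with ATF5 at 0.75, DDIT3 at 1.37, ATF4 at 0.25 and DNAJB9 at -0.39. Of 19 glycolysis genes, 7 rose and 2 fell (adjusted p = 0.131), or 8 and 3 adjusted over the list alone: LDHA rose by 0.45, PKM by 0.25 and GAPDH by 0.29, and HK2 fell by 0.26. Of 15 hypoxia genes, 2 rose and 2 fell (adjusted p = 0.897), or 1 and 2 adjusted over the list alone, namely FAM162A (0.41), VEGFA (0.23), PDK1 (-0.45) and NDRG1 (-0.43).

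Of 16 imprinted genes, 3 rose and 7 fell (adjusted p = 0.537): H19 fell from 3.46 ± 0.47 to 0.73 ± 0.16 CPM and ZDBF2 by 0.54, while SNRPN rose by 0.27. Of 18 genes of 20q11.21, a segment often gained by pluripotent lines, 6 rose and 5 fell (adjusted p = 0.774), with ID1 at 1.60, ASXL1 at -0.62, KIF3B at -0.40 and PLAGL2 at -0.25. Of 50 clustered protocadherins, 13 fell and 3 rose (adjusted p = 0.146), or 10 and 3 adjusted over the list alone; PCDHGB7 fell from 18.2 ± 0.75 to 7.67 ± 0.44 CPM, PCDHGC4 from 11.04 ± 1.40 to 3.63 ± 0.49 CPM, PCDHB16 by 1.21 and PCDHA3 by 0.75, though their exons overlap. Of 38 genes with replication-dependent histone names, 2 rose and 3 fell (adjusted p = 0.963), or 1 and 2 adjusted over the list alone. PolyA libraries hold little of these mRNAs. HIST2H2BD was at -0.92 and HIST2H2BC at -0.77, both annotated as pseudogenes, HIST1H2AC at 0.57 and HIST1H3E at 0.67. After the length corrections 2 rose and 8 fell with exonic length, and 2 rose and 7 fell with transcript length. The median went from 0.025 to -0.119 and -0.1 (adjusted p = 0.282 and 0.256). Of 13 mitochondrially encoded mRNAs, 4 fell and 1 rose (adjusted p = 0.467): MT-ND1 at -0.26, MT-ND2 at -0.25, MT-CYB at -0.23 and MT-ND6 at 0.26. After the length corrections this list was lower past the threshold (adjusted p = 0.00183 with exonic length and 0.00125 with transcript length), at the preset correlation of 0.01. The estimated correlation of its members before correction was 0.718 (adjusted p = 0.836 with an estimated correlation), so these low values may overstate the evidence. No HOX gene passed the expression filter. Adjusted over the list alone, the counts were the same in the 22 lists for which no such count is given.

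Whole chromosomes stayed close to no change. Median log2 fold changes of 23 chromosomes lay between -0.06 on chromosome 18 and 0.08 on chromosome 19. A two-sided exact permutation test of 5 against 5 libraries gave its lowest p on chromosome 19 (0.0159, adjusted p = 0.365). The smallest exact p it allows is 0.0079, so a single shifted chromosome could reach an adjusted p of 0.183 at best over 23, and this test could not have called it. In windows of 50 neighbouring tested genes the median ran from -0.21 (chromosome 10, 84279980 to 92030325) to 0.20 (chromosome 11, 62670273 to 64321811).

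The authors' deposited table lists KCNH2 at a log2 fold change of -0.32. Over 19163 genes, its log2 fold changes had a Pearson correlation of 0.93 and a Spearman correlation of 0.99 with those above, both from the same libraries. With genes of few counts included (32152 genes) the values were 0.55 and 0.84. Of 8331 tested genes under an adjusted p of 0.05 in the authors' deposited table, 8151 passed here as well, each with the same sign. The authors' deposited table marks 1217 genes as called, 446 higher and 771 lower, none with an absolute log2 fold change under 0.585.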

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

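Among the tests here, those of the ribosomal protein list against gene length, of the p53 list without knockout replicate 3, and every correction by transcript length were chosen only after the result was seen.

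The groups differed in 8816 genes. Of 100 splits of the 10 libraries into 5 and 5, out of 126 possible, 1 (the real one) called as many. The highest other called 1, which argues against a chance assignment of these libraries, though every other split mixed the groups. The labels do not say that replicates came from separate cultures, so the splits cannot exclude a chance difference between cultures. Gain or loss of a whole chromosome is argued against by chromosome 19, the furthest from 0, at a median log2 fold change of 0.081. The culture medium stays open: TeSR-E8 is made without lipids or albumin, and the cholesterol list fell in the knockout (median log2 fold change -0.31), as a medium that supplies lipids could bring about. Loss of KCNH2 and the clonal history of the edited cells stay open as well, and since medium and genotype go together in every library they cannot be told apart. A technical difference between the groups was not tested and stays open too. Across genes, transcript length correlated (Spearman) with each library's centred log2 CPM at -0.488 to -0.229 in the knockout and 0.287 to 0.515 in WT.

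The ribosomal protein and p53 lists rose in libraries where short genes were higher as a group. A length trend may account for part of the ribosomal median of 0.33, since the lower of the corrected medians was 0.149, but the corrected scores of the 5 knockout libraries still lay above all WT scores. For p53 targets the lower corrected median was 0.542 against 0.58 before. Their transcripts, at a median of 2602 bases against 2702 over tested genes, left little to correct, so this was not a strong test. The same near-equal length gives a length trend little to act on. Knockout replicate 3 had the highest p53 score, yet without it the median was 0.523 (camera adjusted p = 5.6e-07). Medium, genotype, culture state and a technical difference between the groups remain open for both lists. With an estimated correlation neither list was past the threshold (adjusted p = 0.274 and 0.441).

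In 47 genes the log2 fold change was at least 3 in size with at least 1 CPM in the higher group. Loss or gain of a segment reaching past the gene would be expected to move its neighbours. The median change of 90 neighbouring protein-coding genes, signed by the gene's direction, was 0.076. In 1 of 45 genes both neighbours moved by at least 1. These values argue against large segments for most of these genes, but a segment little longer than the gene could escape them. A median also does not speak for single genes. SOHLH2, beside CCDC169, moved by 6.901 in the same direction, and the neighbours GLT6D1 and LCN9 rose by 9.152 and 6.595. After either length correction 100% of the 45 with a known length kept their fold. The choice of genes with a log2 fold change of at least 3 in size all but fixed that outcome, so it is not a test of the length trend. In bins of genes ordered by transcript length, the median log2 fold change ran only from 0.22 to -0.13. A trend of that size is far smaller than these folds. A clonal difference in silencing between the lines may be a candidate explanation. It was not tested, and the medium and the edit stay open.

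In 377 groups of 5 values that were examined (named genes, list scores and depth measures), 9 held a library far from the other 4; chance flags about 1 in 20, which is 19. In the knockout, PCNA measured 285.4 CPM in replicate 4 against 291.6 to 294.1 CPM, and the fatty acid synthesis score was -0.38 in replicate 5 against -0.28 to -0.26. In WT replicate 1, FOS measured 2.53 CPM against 3.53 to 3.85, CCND1 164.4 CPM against 181.7 to 186.2, PDK1 28.1 CPM against 30.7 to 31.8 and HIST2H2BD 10.7 CPM against 11.8 to 12.2. MYH6 measured 0.99 CPM in WT replicate 5 against 1.1 to 1.139. PNPLA4 stood at 0.029 CPM in WT replicate 4 and CAT at 0.034 CPM in WT replicate 5, a single count each, with the other WT libraries at 0.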

How the results depend on the processing

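Fits without several libraries, with a surrogate variable or with a length correction were added after seeing the data. The counts of genes were 3596 to 4549 higher and 3598 to 4749 lower in every alternative but the test against a log2 fold change of 1 (83 and 93), which asks for larger changes. Similar totals did not mean the same genes. Of the 8816 genes called in the main fit, 7127 stayed called with exonic length and 6780 with transcript length. Without knockout 3, WT 2 and WT 3, 6713 of 8814 stayed called. Past a log2 fold change of 1, no filter gave 411 higher and 597 lower and the stricter filter 166 and 220, since they test more and fewer genes of low counts. Correlations of libraries that share a replicate number were 0.173, -0.157, 0.698, 0.198 and 0.176. Knockout 3 also correlated with WT 2, at 0.532, so it is uncertain whether the numbers pair the samples. With the replicate block 4258 genes were higher and 4300 lower. KCNH2 stayed lower in all alternatives, at -0.35 in the test against 1, which it did not pass. Lists called higher numbered 0 and lists called lower 0 with an estimated correlation; the number higher was 4 without knockout 3, WT 2 and WT 3 and 4 with 1 surrogate variable, and ranged from 2 to 4 when single libraries were left out. The added lists were immediate early genes, ATF4 and unfolded protein response (0.0246 with 1 surrogate variable), naive pluripotency (0.0451 without knockout 3, WT 2 and WT 3) and, with exonic length, glycolysis (0.0488). The number lower was otherwise 3 (transcript length) to 5 (with the calcium channels, as with the block). These numbers hide exchanges of lists. With transcript length the mitochondrially encoded list entered (0.00125), while the potassium channel (0.0558) and fibroblast (0.156) lists dropped out. With exonic length the mitochondrially encoded list entered (0.00183) and the fibroblast list dropped out (0.115). The cause of these differences was not tested. Log2 fold changes against the authors' deposited table had a Pearson correlation of 0.55 without a filter against 0.93, where fold changes of genes with few counts differ. Of named genes, MT-ND6 was the 1 that turned, to -0.052 with the transcript length correction.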

Other observations

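The tests of actin and SRF targets and of YAP/TAZ targets were chosen only after some of the values were seen, and so were all 4 lists named here.

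Metallothionein genes, whose products bind zinc and copper, rose in the knockout in 6 of 6 tested (median log2 fold change 2.99; adjusted p = 2.05e-06, and adjusted p = 0.12 with an estimated correlation). MT1X went from 10.04 ± 1.03 to 34.1 ± 3.23 CPM, MT1F from 2.06 ± 0.29 to 11.1 ± 1.47 CPM and MT2A from 0.80 ± 0.14 to 9.41 ± 2.35 CPM. Of 13 genes of MHC class I presentation, 6 rose and 4 fell (adjusted p = 0.433), with HLA-B up from 27.7 ± 2.74 to 87.6 ± 7.74 CPM, HLA-C up by 0.55 and HLA-G, the form found in trophoblast, down by 0.71. HLA genes are polymorphic and near-identical in parts, so counts may be split among them.

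A hypothesis for the metallothioneins is more available zinc in mTeSR Plus than in TeSR-E8. SLC30A1, a zinc exporter gene driven by the same zinc sensor, rose by 0.24 on the log2 scale (29.3 ± 0.75 to 34.6 ± 5.46 CPM, adjusted p = 0.0452), as that hypothesis predicts. The call is fragile: it was lost in 11 of 22 alternatives, among them the test against a log2 fold change of 1. Leaving out 1 library ended it for 7 of the 10, with adjusted p up to 0.105 in those fits. Zinc was not measured, and the effect may equally come from the genotype.

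Of 21 actin cytoskeleton and SRF target genes, 16 rose and 1 fell (median 0.46, adjusted p = 3.85e-06, and adjusted p = 0.37 with an estimated correlation). ACTA1 rose by 2.38, ACTG2 by 2.38, CNN1 by 1.12 and MYL9 from 103.6 ± 2.72 to 211.1 ± 34.4 CPM. Higher serum response factor activity is a candidate explanation, but the list was written after several of its genes had been seen, so the median of 0.46 cannot test it. Higher YAP/TAZ activity was considered from CCN1 (up by 1.92) and CCN2 (up by 1.46). Of 20 YAP/TAZ targets, 6 rose and 6 fell with a median of 0.051 (adjusted p = 0.728), which leaves it undecided. With each length correction 8 rose and 5 fell, at medians of 0.108 (exonic, adjusted p = 0.513) and 0.128 (transcript, adjusted p = 0.376). The list's mean log2 score over WT ran from -0.082 in knockout replicate 1 to 0.402 in knockout replicate 3.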
